A study of Mus musculus with 12 samples.

How the data were processed

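Total RNA of white adipose tissue (WAT) and brown adipose tissue (BAT) from male C57 mice, 4 months old and kept on chow, was hybridised to Affymetrix mouse gene ST arrays. The mice were ob/ob, which lack leptin and are obese, or ob/ob mice that were also labelled as lacking Cidea and Cidec, called triple mutants here. The 12 arrays formed 4 groups of 3, and each array was put in its group by its title. Nothing in the labels says that the arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

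The values used were the deposited log2 values of 35556 probe sets on each array. The submitters' processing notes name RMA and limma without versions, and the array column names of the authors' expression table name a gene-level RMA algorithm, which adjusts background, quantile normalizes across arrays and summarises probes on the log2 scale. The authors' expression table also holds 12 columns of array values whose names carry a tissue and 7 different numbers, 5 of them under both tissues. These names matched no sample label, so the 12 columns were not used, and only the annotation of that table (symbol, position and probe set category, as deposited) was taken. Ensembl entries in that annotation name mouse build NCBIM37, for 2980 probe sets, and positions are given on that build. The authors' tables of changed genes hold a log2 fold change and an absolute fold change as a ratio for each listed probe set, per the file headers. The authors' term tables hold p-values, Benjamini-adjusted p-values and fold enrichments as ratios, per the file headers, which do not name the tool.

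Of the probe sets, 28350 were of the main category. Of these, 25004 named 1 gene, 2 named several and 3344 named none. Genes were represented by the probe set with the highest mean over all 12 arrays, which left 21618 genes, 1833 of them with more than 1 probe set. Set against the given table of mouse gene symbols, 18651 genes matched directly, 2222 by an older symbol and 745 not at all. The latter kept the name in the deposited annotation. No gene was left out for low signal in the main analysis, and 15221 genes had a mean log2 value of at least 5. Without scanner files, background detection per probe was not analysed, and the 45 antigenomic control probe sets were its measure. For a group below the highest of these controls, a log2 change is no fold estimate. Some such groups are unmarked, as for Ucp1, Gpr50, Atp6v0d2 and S100a6. The number of arrays limits the precision of each value.

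The tests were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to all 12 arrays, with 4 group means, 8 residual degrees of freedom and 3.47 prior degrees of freedom. The comparisons were triple mutant minus ob/ob in WAT and in BAT, the difference between these 2 effects, and BAT minus WAT in each genotype. A gene was called at an adjusted p under 0.05 (limma, two-sided, Benjamini-Hochberg over the 21618 genes). Gene lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 42 lists, and again with the correlation estimated from the data. Camera compares the genes of a list with all other genes. Members were counted by the test over all genes and adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. In simulated data with changed genes of known size among 21618 genes, limma recovered 84% of genes simulated at a log2 change of 1 and 100% at 2 in WAT, and 86% and 100% in BAT.

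The gene lists, the tests, the alternatives and the rule for named genes were chosen before the data were examined. The lists covered metabolic pathways and mitochondria, markers of adipocytes and of the other cell types that fat tissue can hold, and immune, matrix, stress, cell cycle, hypoxia and clock genes. Some genes stand in several lists.

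For each genotype comparison the named genes were 11 fixed in advance (Cidea, Cidec, Cideb, Ucp1, Ppara, Ppargc1a, Pnpla2, Lep, Adipoq, Pparg and 1 not reported here), the 12 with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap and whose higher group had a mean of at least 6, and the 4 members of each list with the smallest p. Predicted genes, RIKEN clones, small RNAs, pseudogenes, antigen receptor segments and the olfactory, vomeronasal and urinary protein families were left out. Groups of 3 against 3 do not overlap in 10% of cases by chance. For the difference between tissues 8 genes per direction were taken, and for each tissue difference 5. Not every gene that the rule gives is named.

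Replicate numbers recur across groups in the titles. Across tissues, arrays of the same genotype and number deviated together from their group means (r = 0.22, 0.22 and 0.16 in ob/ob, 0.15, 0.21 and 0.19 in triple mutants, across genes), each above its correlation with the other numbers of the other tissue, so these numbers pair the samples across tissues. The source of this pairing is the data and not a statement in the labels.

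Alternatives were a filter at a mean log2 value of 5, all main probe sets without collapsing, the mean of a gene's probe sets, median centring of arrays, quantile normalization within a tissue, eBayes with trend and robust settings, array weights, only the 6 arrays of a tissue or genotype, replicate blocks, a 1.5-fold threshold, the fry test for lists, and each array left out in turn. A covariate for skeletal muscle transcripts, and the block of genotype and number in the list tests of the difference between tissues, were added after the data were seen. Leaving out an array leaves a group with 2 arrays, whose spread is pooled with that of the other groups.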

Results

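Gene expression was measured in white adipose tissue (WAT), the main fat store, and brown adipose tissue (BAT), which burns fat to make heat, of obese ob/ob mice that lack the hormone leptin. The other genotype was ob/ob mice labelled as also lacking Cidea and Cidec, a pair of lipid droplet proteins that promote droplet fusion and growth, called triple mutants here. Each of the 4 groups (a genotype in a tissue) held 3 arrays, and the labels used here do not name the white depot. The share of genes above the highest antigenomic control, a measure of background signal, ran from 19.5% on ob/ob BAT array 3 to 32.3% on ob/ob WAT array 2. The comparisons asked which genes differ between the labelled genotypes in each fat tissue, whether these differences are alike in WAT and BAT, and how far WAT and BAT differ within a genotype.

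Cidea, a droplet protein typical of brown fat (chromosome 18, 67503258 to 67527432, build NCBIM37), had a higher signal in triple mutant WAT than in ob/ob WAT, at 9.13 ± 0.82 against 5.31 ± 0.39 (log2, SD, n = 3; log2 change 3.83, SE 0.32, limma adjusted p = 6.53e-06). The ob/ob value lay below the highest antigenomic control of those arrays (7.40 to 7.57). In BAT Cidea was high, at 11.45 ± 0.06 in ob/ob and 11.32 ± 0.06 in triple mutants (log2 change −0.13, SE 0.32, adjusted p = 0.836, or 0.365 with BAT arrays alone). Cidec, the droplet protein typical of white fat (chromosome 6, 113374628 to 113385749), was at 11.56 ± 0.31 in ob/ob WAT, 11.12 ± 0.11 in triple mutant WAT, 10.92 ± 0.29 in ob/ob BAT and 10.81 ± 0.02 in triple mutant BAT. Its log2 change was −0.44 in WAT (SE 0.16, limma adjusted p = 0.0526) and −0.11 in BAT (SE 0.16, adjusted p = 0.701). The BAT value was −0.27, 0.00 and −0.05 without ob/ob BAT array 1, 2 and 3, and the WAT value −0.29 without ob/ob WAT array 3. The related gene Cideb (chromosome 14, 56372882 to 56377295), best known from liver, rose in WAT by a log2 change of 1.63 (SE 0.28, adjusted p = 0.000759) and had a log2 change of 0.70 in BAT (SE 0.28, adjusted p = 0.111). The Cidec signal passed the threshold in WAT without ob/ob WAT array 1 (log2 change −0.60, adjusted p = 0.0139), with quantile normalization within the tissue (−0.51, adjusted p = 0.0348), and with 4 other settings. Which parts of Cidea and Cidec the probe sets cover relative to the deleted parts is not given in the sources used here, so these signals check neither the genotype labels nor the loss of the transcripts.

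**Figure D1:**
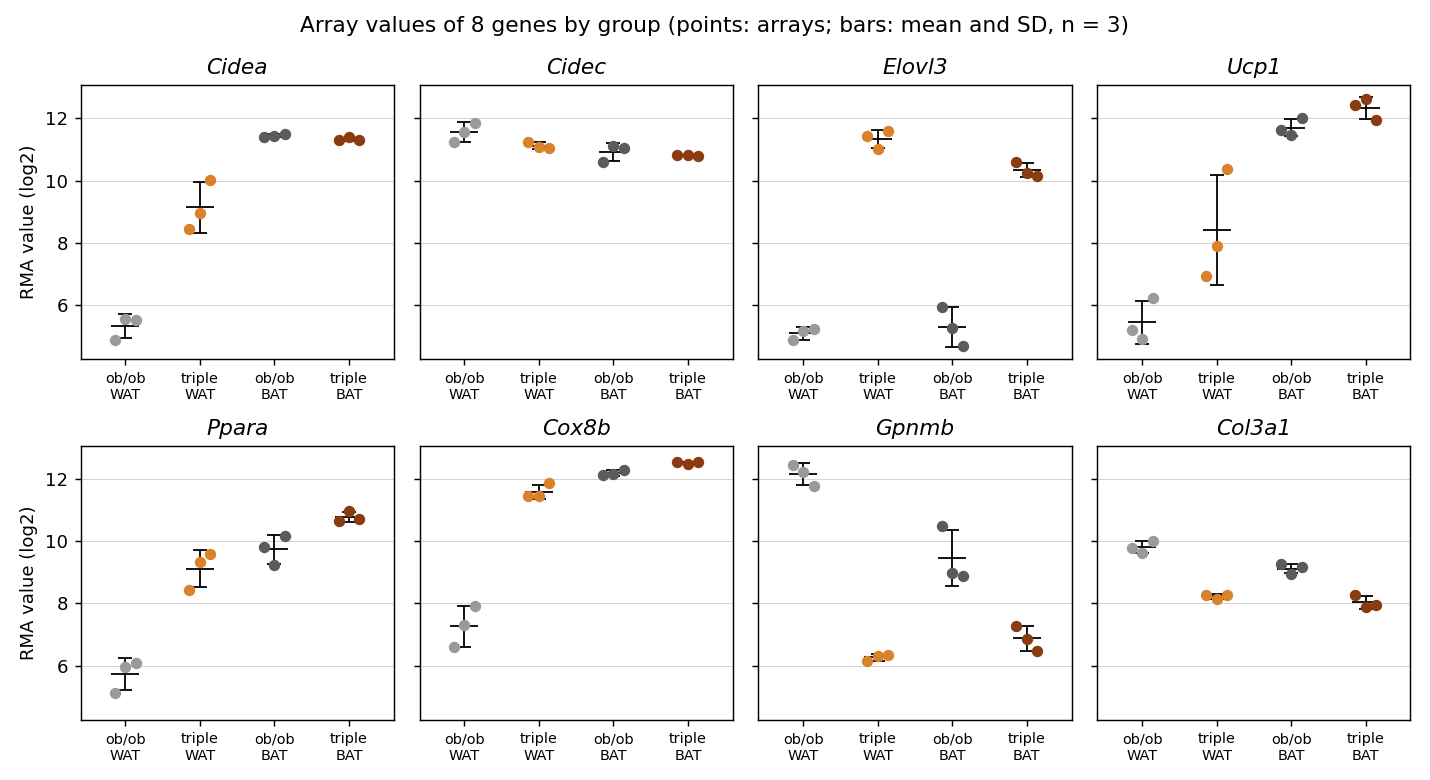
Log2 signal of 8 genes on each of the 12 arrays by group, with points for single arrays, bars for the mean and error lines for the SD of 3 arrays. Elovl3 lies at 5.08 in ob/ob WAT and 11.34 in triple mutant WAT, while Cidea is near 11.45 in ob/ob BAT and varies among triple mutant WAT arrays (SD 0.82).

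In WAT of triple mutants, Elovl3 and genes of fatty acid oxidation and the respiratory chain rose, and genes of macrophages fell. Elovl3, a fatty acid elongase abundant in active brown fat (chromosome 19, 46206389 to 46210184), rose from 5.08 ± 0.20, below the highest control as well, to 11.34 ± 0.30 (log2, SD, n = 3; log2 change 6.26, SE 0.27, limma adjusted p = 2.66e-07). Atp6v0d2, a proton pump subunit of osteoclasts and lipid-laden macrophages (chromosome 4, 19803985 to 19849713), fell from 11.71 ± 0.15 to 4.73 ± 0.34 (log2 change −6.98, SE 0.43, adjusted p = 1.62e-06). Further large rises were those of Tlcd4 (log2 change 5.11), Cyp2b10, a cytochrome P450 (4.37), and Cox8b, a cytochrome c oxidase subunit of brown fat and muscle (4.33). They were followed by Cpt1b, which lets fatty acids enter mitochondria (3.70), and Gsta4 (3.67), with adjusted p from 1.41e-06 to 0.000115. Further large falls were those of Mmp12, macrophage elastase (−6.42), Gpnmb, a glycoprotein of lipid-laden macrophages (−5.89), and Il7r, the interleukin 7 receptor (−5.39). Lower as well were Gpr50, an orphan receptor (−5.28), Stap1 (−5.00), and Itgax, the integrin CD11c of inflammatory macrophages and dendritic cells (−4.60), with adjusted p from 6.82e-08 to 7.10e-06. In all, limma called 7418 of 21618 genes (34.3%), of which 3809 rose and 3609 fell.

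Among the genes of fat metabolism fixed in advance, Ppara, the receptor that drives fatty acid oxidation genes, rose in WAT by a log2 change of 3.40 (SE 0.33, limma adjusted p = 1.48e-05), and Ppargc1a, a coactivator of mitochondrial biogenesis, by 2.85 (SE 0.31, adjusted p = 2.91e-05). Ucp1, the uncoupling protein that makes heat in brown fat (chromosome 8, 85814251 to 85822351), rose from 5.43 ± 0.69 to 8.40 ± 1.77 (log2 change 2.97, SE 0.67, adjusted p = 0.0044), still below its 11.70 ± 0.27 in ob/ob BAT. The triple mutant WAT arrays had Ucp1 values of 6.94, 7.89 and 10.36. Pnpla2, the lipase that starts triglyceride breakdown, rose by 0.98 (adjusted p = 0.000163), and Adipoq, the hormone adiponectin, by 1.33 (adjusted p = 0.000667). Lep, the leptin gene, had a log2 change of −0.16 (adjusted p = 0.502). Pparg, the master regulator of fat cells, had a log2 change of 0.38 that just passed (SE 0.13, adjusted p = 0.0453). That call was lost without ob/ob WAT array 1 (log2 change 0.20, adjusted p = 0.148) or 2 (0.0628), or triple mutant WAT array 1 (0.109), 2 (0.112) or 3 (0.0623), and with quantile normalization within the tissue (0.0750) or the 6 WAT arrays alone (0.118). For each WAT gene described as risen or fallen, all 3 arrays of a genotype lay above all 3 of the other, which happens in 10% of cases by chance.

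The genes of oxidative phosphorylation rose in WAT in all of its complexes. All 38 measured genes of complex I rose (38 adjusted over the list alone), among them Ndufb8 (log2 change 1.94) and Ndufa1 (1.77). The median log2 change was 1.24 (camera adjusted p = 1.84e-23, adjusted p = 0.15 with an estimated correlation). All 14 genes of complexes II and III rose (14 adjusted over the list alone), such as Uqcrfs1, the Rieske iron-sulfur protein (1.99). Their median was 1.38 (camera adjusted p = 1.03e-12, adjusted p = 0.15 with an estimated correlation). Of 21 genes of complex IV, 20 rose (20 adjusted over the list alone), including Cox6a1 (1.53) and Cox5b (1.32). Here the median was 0.90 (camera adjusted p = 8.94e-12, adjusted p = 0.15 with an estimated correlation). Of 18 genes of ATP synthase, 16 rose and 1 fell (the same adjusted over the list alone). Atp5o rose by 1.69, and the gene that fell was Atpif1 (−1.18), which encodes an inhibitor of the enzyme. The ATP synthase median was 0.89 (camera adjusted p = 1.92e-09, adjusted p = 0.15 with an estimated correlation). All 22 genes of the TCA cycle, which feeds the respiratory chain, rose (22 adjusted over the list alone), such as Idh3g (1.61). The TCA cycle median was 1.46 (camera adjusted p = 9.99e-17, adjusted p = 0.15 with an estimated correlation). The mitochondrial ribosome rose in 63 of 73 genes with none lower (68 adjusted over the list alone), with Mrpl45 at 1.31. The median was 0.69 (camera adjusted p = 1.07e-18, adjusted p = 0.181 with an estimated correlation).

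Mitochondrial and peroxisomal fat oxidation genes rose in WAT. Of 22 genes of mitochondrial fatty acid oxidation 21 rose (21 adjusted over the list alone), such as Acadvl (2.57). Their median log2 change was 1.56 (camera adjusted p = 2.65e-14, adjusted p = 0.15 with an estimated correlation). Of 28 genes of peroxisomal fatty acid oxidation 22 rose and 1 fell (the same adjusted over the list alone), such as Pecr (2.03) and Cat, catalase (0.88). The median was 1.25 (camera adjusted p = 9.15e-12, adjusted p = 0.15 with an estimated correlation). Of the 22 peroxins, which build peroxisomes, 17 rose and 1 fell (the same adjusted over the list alone), with Pex3 at 1.40 and Pex19 at 1.42. The median was 0.73 (camera adjusted p = 1.66e-07, adjusted p = 0.15 with an estimated correlation). The PPAR alpha targets rose in 18 of 31 genes and fell in 1 (19 and 2 adjusted over the list alone), including Ucp3 (2.70). The median was 1.03 (camera adjusted p = 5.67e-07, adjusted p = 0.187 with an estimated correlation). Brown and beige thermogenic genes rose in 19 of 26 and fell in 1 (21 and 1 adjusted over the list alone), among them Cox7a1 (3.38). The median was 1.5 (camera adjusted p = 2.57e-09, adjusted p = 0.15 with an estimated correlation).

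Genes that store and release fat also rose in WAT. Lipolysis genes rose in 17 of 21 and fell in 1 (the same adjusted over the list alone), such as Ces1d (2.80), Pde3b, which restrains lipolysis under insulin (1.67), and G0s2, an inhibitor of Pnpla2 (1.61). Their median log2 change was 1.04 (camera adjusted p = 4.70e-08, adjusted p = 0.157 with an estimated correlation). Fatty acid and triglyceride synthesis rose in 19 of 28 genes and fell in 2 (21 and 2 adjusted over the list alone), with Pck1 (3.47), Acacb (2.82), and Dgat1, which makes triglycerides (1.53). The median was 1.12 (camera adjusted p = 1.66e-07, adjusted p = 0.203 with an estimated correlation). Lipid droplet genes rose in 11 of 20 and fell in 1 (11 and 4 adjusted over the list alone), among them Plin5, a droplet coat protein (2.07). The median was 0.65 (camera adjusted p = 0.00904, adjusted p = 0.187 with an estimated correlation). Cholesterol synthesis rose in 14 of 24 and fell in 1 (14 and 2 adjusted over the list alone), with Insig1 at 1.67. The median was 0.58 (camera adjusted p = 0.00161, adjusted p = 0.293 with an estimated correlation). Glucose uptake and glycolysis rose in 15 of 23 and fell in 1 (15 and 2 adjusted over the list alone), including Slc2a4, the insulin-responsive glucose transporter (1.86). The median was 0.61 (camera adjusted p = 1.89e-05, adjusted p = 0.15 with an estimated correlation). Branched-chain amino acid catabolism rose in 18 of 19 genes (18 adjusted over the list alone), with Bckdha at 1.80. The median was 1.62 (camera adjusted p = 1.30e-12, adjusted p = 0.157 with an estimated correlation). Adipocyte markers rose in 14 of 18 (14 adjusted over the list alone), among them Adig, adipogenin (1.88). The median was 0.99 (camera adjusted p = 5.27e-06, adjusted p = 0.226 with an estimated correlation).

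Macrophage markers fell most among the lists in WAT. Of 25 markers 24 fell (25 adjusted over the list alone), and their mean fell from 10.1 ± 0.23 to 6.75 ± 0.10 (SD, n = 3). The median log2 change was −3.31 (camera adjusted p = 1.19e-21, adjusted p = 0.15 with an estimated correlation). Lysosome and autophagy genes fell in 23 of 32 and rose in 2 (23 and 3 adjusted over the list alone), such as Ctsk, cathepsin K (−4.07), Lipa, the lysosomal acid lipase (−2.37), and Hexa (−1.75). The median was −0.71 (camera adjusted p = 2.61e-10, adjusted p = 0.15 with an estimated correlation). Cytokines and chemokines fell in 14 of 27 and rose in 2 (the same adjusted over the list alone), with Il1rn (−4.05), and Ccl9 (−3.67). The median was −0.63 (camera adjusted p = 1.89e-05, adjusted p = 0.203 with an estimated correlation). Cell cycle genes fell in 27 of 33 and rose in 1 (29 and 1 adjusted over the list alone), including Ccnb2, cyclin B2 (−2.45), and Rrm2 (−2.13). The median was −1.56 (camera adjusted p = 1.30e-12, adjusted p = 0.229 with an estimated correlation). Extracellular matrix genes fell in 19 of 28 (22 adjusted over the list alone), with the collagens Col6a3 (−1.64) and Col3a1 (−1.58) and periostin, Postn (−2.31). The median was −1.13 (camera adjusted p = 4.63e-11, adjusted p = 0.15 with an estimated correlation). Fibroblast and preadipocyte markers fell in 9 of 17 and rose in 1 (10 and 1 adjusted over the list alone), such as Mfap5 (−1.48). The median was −0.51 (camera adjusted p = 0.00289, adjusted p = 0.226 with an estimated correlation). Immediate early genes fell in 9 of 20 (10 adjusted over the list alone), among them Egr2 (−2.80) and Fos (−2.04). The median was −0.33 (camera adjusted p = 0.000148, adjusted p = 0.157 with an estimated correlation).

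Markers of other cell types moved by smaller amounts in WAT. T and NK cell markers fell in 6 of 16 (6 adjusted over the list alone), with Thy1 at −0.94. The median log2 change was −0.32 (camera adjusted p = 0.00197, adjusted p = 0.347 with an estimated correlation). Neutrophil and mast cell markers fell in 7 of 15 (8, with 1 higher, adjusted over the list alone), and the named members, Cpa3 (−3.07) and Mcpt4 (−2.47), are proteases of mast cells. The median was −0.47 (camera adjusted p = 0.0182, adjusted p = 0.23 with an estimated correlation). Endothelial markers rose in 8 of 17 (9 adjusted over the list alone), with Kdr, a VEGF receptor, at 1.35. The median was 0.44 (camera adjusted p = 0.000494, adjusted p = 0.328 with an estimated correlation). Erythroid markers rose in 6 of 10 (6 adjusted over the list alone), such as Hbb-b1, a globin (1.37). The median was 0.40 (camera adjusted p = 0.00263, adjusted p = 0.157 with an estimated correlation). Hypoxia response genes rose in 8 of 19 and fell in 1 (the same adjusted over the list alone), among them Vegfa, the growth factor of vessels (1.70). The median was 0.22 (camera adjusted p = 0.0244, adjusted p = 0.15 with an estimated correlation). Mesothelial markers rose in 6 of 12 (7 adjusted over the list alone). The median was 0.47 (camera adjusted p = 0.0259, adjusted p = 0.454 with an estimated correlation). The mesothelial call was lost without ob/ob WAT array 1 (adjusted p = 0.150) or 3 (0.0506), without triple mutant WAT array 2 (0.0884) and with the filter on dim genes (0.0929), and that filter also ended the call of neutrophil and mast cell markers (0.111). Without ob/ob WAT array 1 the endothelial median was 0.23 and that of neutrophil and mast cell markers −0.31, and without triple mutant WAT array 2 that of T and NK cell markers −0.19. Called T and NK cell markers were 2 without ob/ob WAT array 1 or 2 and 3 without triple mutant WAT array 1 or 2, and mesothelial markers 1 without ob/ob WAT array 1 and 2 without ob/ob WAT array 3 or triple mutant WAT array 1 or 2.

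In all, 31 of 42 lists passed in WAT (median 26 over other array splits), 22 higher and 9 lower in triple mutants. None passed with an estimated correlation (lowest adjusted p = 0.15). With fry, which asks whether a list's genes move one way, 37 passed, including all 31. The interferon response had 1 gene higher and 6 lower of 25 (the same adjusted over the list alone; median −0.28, camera adjusted p = 0.0565). It passed without ob/ob WAT array 2 (adjusted p = 0.0482) or 3 (0.0219) and without triple mutant WAT array 1 (0.00217). White fat and visceral depot genes rose in 9 of 15 and fell in 2 (the same adjusted over the list alone), with Agt, angiotensinogen, up by 2.52 and the imprinted genes Mest (−2.83) and Nnat (−2.79) lower. The median was 0.54 (camera adjusted p = 0.101). The integrated stress and unfolded protein response had 7 higher and 10 lower of 26 (8 and 11 adjusted over the list alone), with Asns, which makes asparagine, up by 1.93 and the stress factor Atf3 at −4.11. The median was −0.28 (camera adjusted p = 0.136). The antioxidant response had 9 higher and 9 lower of 26 (10 and 9 adjusted over the list alone), and Nfe2l2, the factor NRF2 itself, was at −0.74 (limma adjusted p = 0.000143). The median was 0.00 (camera adjusted p = 0.668). The circadian clock (camera adjusted p = 0.18), B cell (0.193), developmental brown fat (0.492), mammary and skin epithelium (0.429) and Schwann cell and nerve lists (0.8) did not pass, and Jchain was at −1.99. No gonadal or testis marker of 17 (camera adjusted p = 0.677) and no skeletal muscle marker of 21 (camera adjusted p = 0.768) was called by limma in WAT, over all genes or adjusted over the list alone. As seen only after the values were known, the gonadal and testis list had a mean of 4.89 on triple mutant WAT array 3 against 4.11 to 4.38 on the other WAT arrays, and Prm1, a sperm protein, 8.45 against 5.63 to 6.93. Without that array, which was also the highest of WAT for Ucp1, 6857 genes were called in WAT.

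**Figure D2:**
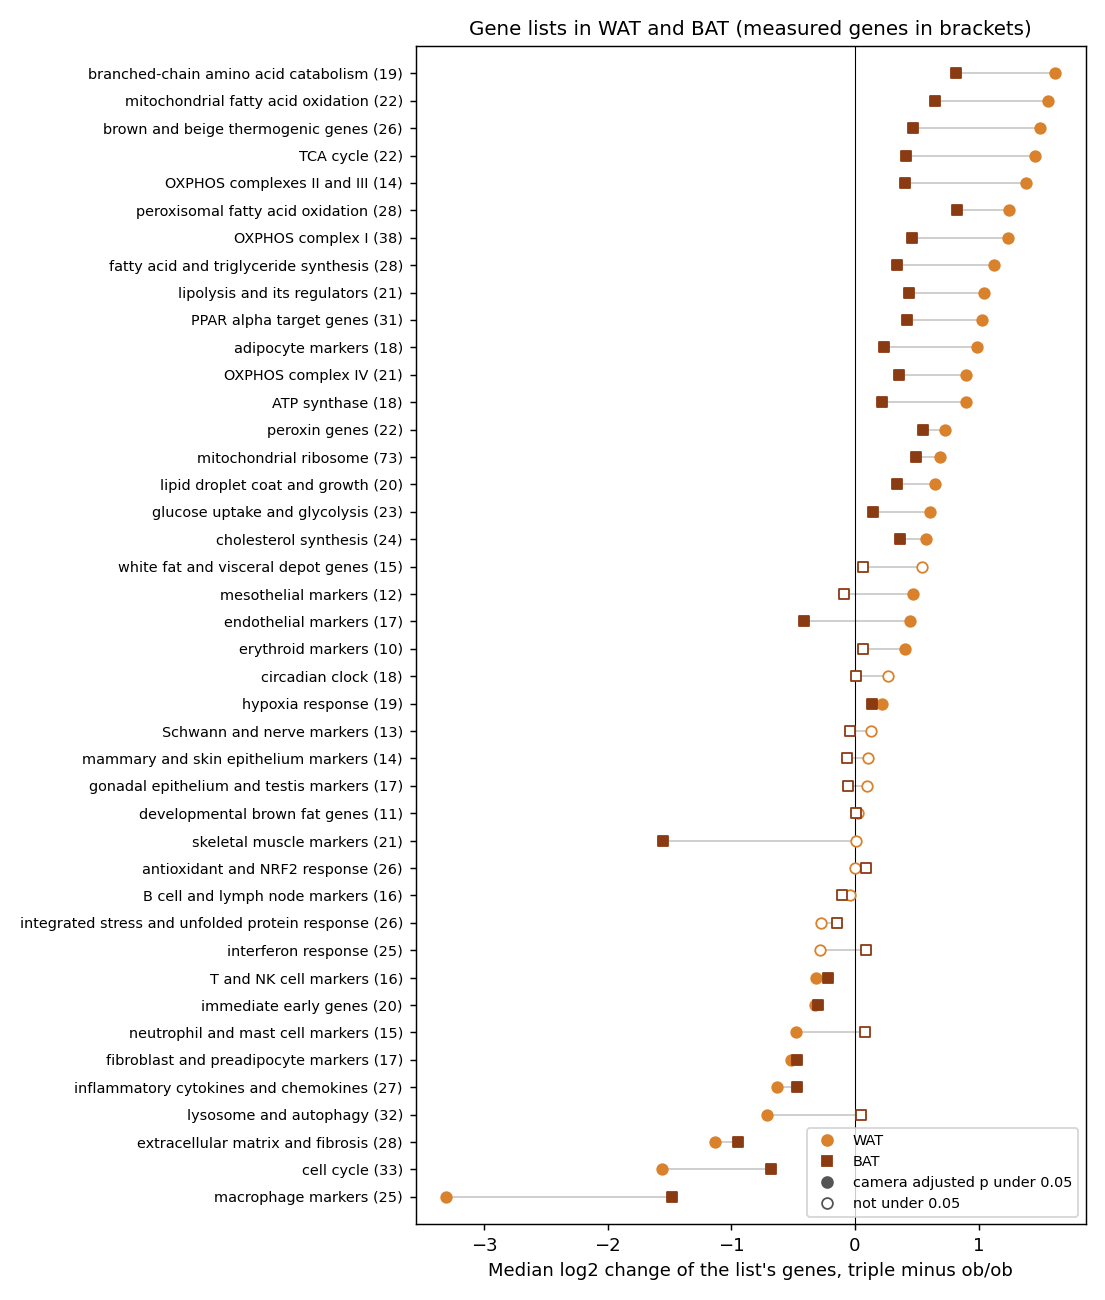
Median log2 change, triple mutant minus ob/ob, of the 42 gene lists in WAT (circles) and BAT (squares), with filled symbols where the camera adjusted p was under 0.05. Macrophage markers lie at −3.31 in WAT and −1.48 in BAT, and TCA cycle genes at 1.46 and 0.41.

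In BAT of triple mutants, genes of peroxisomes and fatty acid oxidation rose, and macrophage and matrix genes fell. Elovl3 rose from 5.29 ± 0.63, below the highest antigenomic control of those arrays (7.83 to 8.13), to 10.34 ± 0.24 (log2, SD, n = 3; log2 change 5.05, SE 0.27, limma adjusted p = 1.13e-05). Hyal1, which degrades hyaluronan (chromosome 9, 107479283 to 107482478), rose from 7.64 ± 0.11 to 9.54 ± 0.17 (log2 change 1.90, SE 0.11, adjusted p = 1.13e-05). Its ob/ob value also lay below the highest control. In turn S100a6, a calcium-binding protein (chromosome 3, 90416816 to 90418337), fell from 9.40 ± 0.39 to 6.22 ± 0.42 (log2 change −3.18, SE 0.22, adjusted p = 7.56e-05). Further rises were those of Cyp2b10 (log2 change 3.46), Eci3, a peroxisomal enoyl-CoA isomerase (2.83), Lipf (2.63), Tlcd4 (2.18), Adtrp (2.08) and Echdc1 (2.01), with adjusted p from 0.00024 to 0.00579. Further falls were those of Mmp12 (−3.15), Gpnmb (−2.58), Mest (−2.54), Nnat (−2.41), Ccl9 (−2.37), Cd52 (−2.35) and Lgals3, galectin 3 of macrophages (−2.35), with adjusted p from 0.000473 to 0.00686. Limma called 3760 of 21618 genes (17.4%), with 2251 higher and 1509 lower. With each array centred on its median, which added 0.10 to every log2 change (median of all genes 0.07 in place of −0.03), the calls were 3424 higher and 929 lower (78.7% higher in place of 59.9%). Without triple mutant BAT array 3, 2466 genes were called, and 3603 with the muscle marker mean as a covariate, which was added after the data were seen.

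Among the genes of fat metabolism fixed in advance, Ucp1 in BAT was at 11.70 ± 0.27 in ob/ob and 12.34 ± 0.34 in triple mutants (SD, n = 3, log2 change 0.64, limma adjusted p = 0.562). That p pools the spread over both tissues, and the Ucp1 SD was 1.77 in triple mutant WAT. It therefore does not tell whether Ucp1 was unchanged in BAT. Neither Ppargc1a, with a log2 change of 0.38 (adjusted p = 0.441), nor Pnpla2 (0.03, adjusted p = 0.912) nor Pparg (0.08, adjusted p = 0.752) passed in BAT. Adipoq had a log2 change of 0.43 (adjusted p = 0.218, and 0.0351 with the 6 BAT arrays alone). Ppara just passed, with a log2 change of 1.05 (SE 0.33, adjusted p = 0.0471). The Ppara call was lost without ob/ob BAT array 1 (adjusted p = 0.0897) or 2 (0.134) and without triple mutant BAT array 1 (0.0840), 2 (0.131) or 3 (0.0991), and with 5 of the other settings, such as quantile normalization within the tissue (0.0823). Lep had a log2 change of −0.61 (adjusted p = 0.0236), a call lost without ob/ob BAT array 1 (0.0534) or 2 (0.0670) and without triple mutant BAT array 1 (0.0794) or 3 (0.0744). Skeletal muscle transcripts differed between the BAT arrays: the mean log2 value of 21 muscle markers was 7.37, 10.8 and 10.6 on ob/ob BAT arrays 1, 2 and 3, and 10.3, 7.87 and 6.14 on triple mutant BAT arrays 1, 2 and 3. This muscle signal stands beside every BAT gene group described here. The muscle list was lower in triple mutants with camera (median log2 change −1.55, adjusted p = 0.00443, adjusted p = 0.636 with an estimated correlation), although none of its 21 genes was called by limma, over all genes or adjusted over the list alone. That list call was lost without ob/ob BAT array 2 (adjusted p = 0.244) or 3 (0.0616), without triple mutant BAT array 3 (0.345) and with fry (0.309). Its median was −2.63 without ob/ob BAT array 1 (3 genes called), −0.92 without ob/ob BAT array 2, −2.65 without triple mutant BAT array 1 (4 genes called) and −0.54 without triple mutant BAT array 3.

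Peroxisomal fatty acid oxidation rose in BAT in 23 of 28 genes (24 adjusted over the list alone), such as Eci3, Abcd3 (1.18), and Cat (0.79). The median log2 change was 0.83 (camera adjusted p = 4.80e-16, adjusted p = 0.216 with an estimated correlation). Peroxins rose in 13 of 22 (14 adjusted over the list alone), with Pex3 at 1.14 and Pex19 at 1.0. The median was 0.55 (camera adjusted p = 5.88e-08, adjusted p = 0.216 with an estimated correlation). Mitochondrial fatty acid oxidation rose in 17 of 22 (19 adjusted over the list alone), including Acot2 (1.60), and Eci2 (1.19). The median was 0.65 (camera adjusted p = 8.63e-12, adjusted p = 0.266 with an estimated correlation). PPAR alpha targets rose in 13 of 31 (14 adjusted over the list alone), with Ucp3 at 1.66. Their median was 0.42 (camera adjusted p = 7.26e-06, adjusted p = 0.266 with an estimated correlation). Brown and beige thermogenic genes rose in 10 of 26 (12, with 1 lower, adjusted over the list alone), with Gk, glycerol kinase, at 1.44. Their median was 0.47 (camera adjusted p = 7.62e-06, adjusted p = 0.266 with an estimated correlation). Branched-chain amino acid catabolism rose in 17 of 19 (19 adjusted over the list alone), among them Mccc1 (1.34). The median was 0.81 (camera adjusted p = 1.41e-13, adjusted p = 0.266 with an estimated correlation). Cholesterol synthesis rose in 9 of 24 (10, with 1 lower, adjusted over the list alone), with Insig1 at 1.38. The median was 0.36 (camera adjusted p = 2.71e-05, adjusted p = 0.266 with an estimated correlation). Fatty acid and triglyceride synthesis rose in 9 of 28 and fell in 1 (11 and 1 adjusted over the list alone; median 0.34, camera adjusted p = 0.000582, adjusted p = 0.439 with an estimated correlation, and 0.0881 with fry), and the gene that fell was Scd1, a fatty acid desaturase (−1.77, and −1.16 without triple mutant BAT array 3). Lipid droplet genes rose in 7 of 20 (8 adjusted over the list alone), with Ldah (0.81) and Bscl2, seipin (0.77). The median was 0.34 (camera adjusted p = 0.000264, adjusted p = 0.216 with an estimated correlation). Lipolysis genes rose in 7 of 21 (12, with 2 lower, adjusted over the list alone), with Prkar2b at 0.69. The median was 0.44 (camera adjusted p = 0.000173, adjusted p = 0.344 with an estimated correlation). With 1 BAT array left out, called members were 10 in mitochondrial fatty acid oxidation (without triple mutant 3), 5 (ob/ob 2) or 6 (triple mutant 1 or 2) in the thermogenic list, 11 in branched-chain amino acid catabolism (ob/ob 1 or triple mutant 3), 5 (ob/ob 1 or 3) or 4 (triple mutant 2 or 3) in fatty acid synthesis, and 3 (ob/ob 3 or triple mutant 2) or 4 (triple mutant 3) in lipolysis.

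Respiratory chain genes rose in BAT as well. Complex I rose in 25 of 38 genes (33 adjusted over the list alone), with Ndufb10 at a log2 change of 0.95. Its median log2 change was 0.47 (camera adjusted p = 1.05e-15, adjusted p = 0.266 with an estimated correlation). Complexes II and III rose in 10 of 14 (14 adjusted over the list alone), with Uqcrfs1 at 0.94. Their median was 0.41 (camera adjusted p = 1.16e-07, adjusted p = 0.266 with an estimated correlation). Complex IV rose in 9 of 21 with 1 lower (13 and 1 adjusted over the list alone), with Cox17 at 1.03. Its median was 0.36 (camera adjusted p = 7.31e-06, adjusted p = 0.266 with an estimated correlation). The mitochondrial ribosome rose in 51 of 73 (58 adjusted over the list alone), with Mrpl45 at 0.90. The median was 0.49 (camera adjusted p = 3.97e-21, adjusted p = 0.266 with an estimated correlation). TCA cycle genes rose in 10 of 22 (15 adjusted over the list alone), such as Suclg2 (1.16) and Dld (1.05). The median was 0.41 (camera adjusted p = 1.17e-08, adjusted p = 0.292 with an estimated correlation). Adipocyte markers rose in 4 of 18 (5 adjusted over the list alone), a call lost with quantile normalization within the tissue (0.0837) and with fry (0.112). The median was 0.23 (camera adjusted p = 0.00185, adjusted p = 0.449 with an estimated correlation). Of 18 ATP synthase genes 5 rose and 2 fell (9 and 3 adjusted over the list alone), and Atpif1 was again lower (−0.96). The median was 0.22 (camera adjusted p = 0.0125, adjusted p = 0.458 with an estimated correlation). Glucose uptake and glycolysis rose in 4 of 23 (4 adjusted over the list alone), with Insr, the insulin receptor, at 0.51. The median was 0.15 (camera adjusted p = 0.0125, adjusted p = 0.266 with an estimated correlation). Hypoxia genes rose in 5 of 19 (6 adjusted over the list alone), with Pfkfb3 at 1.79. The median was 0.14 (camera adjusted p = 0.03, adjusted p = 0.216 with an estimated correlation). These last 3 calls were lost without ob/ob BAT array 1 (adjusted p = 0.141 for ATP synthase, 0.146 for glycolysis and 0.0735 for hypoxia), with the filter on dim genes (0.0604 each) and with quantile normalization within the tissue (0.310, 0.307 and 0.146). The hypoxia call was also lost without triple mutant BAT array 3 (0.0522), and the ATP synthase call with fry (0.0747). The median was 0.25 for glycolysis without ob/ob BAT array 3, and for hypoxia 0.06 and 0.31 without ob/ob BAT array 1 and 3, and 0.22 and 0.40 without triple mutant BAT array 1 and 2. Called members without ob/ob BAT array 1 were 13 in complex I, 2 in complexes II and III, 5 in complex IV, 33 in the ribosome, 4 in the TCA cycle, 2 in adipocytes, 2 in ATP synthase and 3 in hypoxia. Without triple mutant BAT array 3 they were 12 in complex I, 2 in complexes II and III, 5 in complex IV, 4 in the TCA cycle, 0 in adipocytes and 1 in ATP synthase. Without triple mutant BAT array 2 they were 4 in complexes II and III, 5 in complex IV, 6 in the TCA cycle, 1 in adipocytes, 2 in ATP synthase, 2 in glycolysis and 3 in hypoxia, and without array 1, 5 in complexes II and III, 0 in adipocytes and 3 in hypoxia. Without ob/ob BAT array 2 or 3, adipocytes had 1, glycolysis 2 (array 2) and ATP synthase 3 (array 3).

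Macrophage markers fell in BAT in 23 of 25 genes (25 adjusted over the list alone), with Csf1r (−1.63) and Mrc1 (−1.44). The median log2 change was −1.48 (camera adjusted p = 4.36e-16, adjusted p = 0.216 with an estimated correlation). Extracellular matrix genes fell in 20 of 28 (25 adjusted over the list alone), with Col1a1 (−1.27), Col6a3 (−1.26) and Col3a1 (−1.08). The median was −0.94 (camera adjusted p = 2.60e-15, adjusted p = 0.216 with an estimated correlation). Fibroblast and preadipocyte markers fell in 10 of 17 (11 adjusted over the list alone), among them Pcolce (−1.56), Dpt (−1.20) and Dlk1, a preadipocyte factor (−0.80). The median was −0.47 (camera adjusted p = 5.32e-06, adjusted p = 0.216 with an estimated correlation). Cytokines and chemokines fell in 7 of 27 (8, with 1 higher, adjusted over the list alone), with Ccl6 at −2.03. The median was −0.47 (camera adjusted p = 0.000997, adjusted p = 0.369 with an estimated correlation). Immediate early genes fell in 4 of 20 (5 adjusted over the list alone), with Fos (−1.18) and Myc (−0.86). The median was −0.30 (camera adjusted p = 0.0022, adjusted p = 0.266 with an estimated correlation). Cell cycle genes fell in 12 of 33 (22 adjusted over the list alone). The median was −0.68 (camera adjusted p = 5.11e-08, adjusted p = 0.437 with an estimated correlation). Endothelial markers fell in 6 of 17 and rose in 1 (8 and 1 adjusted over the list alone), with Robo4 at −0.59, and the marker that rose was Kdr (0.89). The median was −0.41 (camera adjusted p = 0.00153, adjusted p = 0.439 with an estimated correlation). T and NK cell markers fell in 2 of 16 (2 adjusted over the list alone), with Thy1 at −1.29. The median was −0.22 (camera adjusted p = 0.00684, adjusted p = 0.458 with an estimated correlation). With fry the calls of the last 3 lists were lost (adjusted p = 0.0627 for the cell cycle, 0.0630 for endothelial and 0.0829 for T and NK cell markers). Without ob/ob BAT array 1 the cell cycle median was −0.32, and without triple mutant BAT array 3 those of immediate early genes and cytokines were −0.20 and −0.24. Called members were 7 (without triple mutant BAT array 1) or 5 (array 3) in the cell cycle, 12 (ob/ob 2), 2 (triple mutant 2) or 4 (triple mutant 3) among cytokines, and 1 (ob/ob 1 or triple mutant 3) or 2 (triple mutant 2) among endothelial markers.

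In all, 28 of 42 lists passed in BAT (median 19 over other array splits), 19 higher and 9 lower. Of them 21 passed with fry and none with an estimated correlation (lowest adjusted p = 0.216). Lysosome and autophagy genes did not pass in BAT, with 2 higher and 6 lower of 32 (4 and 7 adjusted over the list alone), although Ctsk fell by 1.44. The median was 0.05 (camera adjusted p = 0.837). Nor did the antioxidant list (camera adjusted p = 0.14, with Gsta4 at 1.70), white fat and visceral depot (0.837), developmental brown fat (0.837), integrated stress response (0.628), Schwann cell and nerve (0.726), erythroid (0.19), circadian clock (0.664), mesothelial (0.24), neutrophil and mast cell (0.713), gonadal or testis (0.422), B cell (0.311) and mammary or skin epithelium lists (0.358). The interferon response (0.224) passed without ob/ob BAT array 1 (0.0310) or triple mutant BAT array 3 (0.0225).

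Genes of the respiratory complexes, the TCA cycle and mitochondrial fatty acid oxidation rose more in WAT than in BAT. Macrophage genes also fell more, and the lysosome list fell only in WAT (tests below). Cox8b rose by 4.33 in WAT and had a log2 change of 0.34 in BAT (limma adjusted p = 0.403, and 0.0428 with the 6 BAT arrays alone), where it was already at 12.19 ± 0.09 in ob/ob mice (SD, n = 3). Its difference was 3.99 (limma adjusted p = 0.00031). The Cidea signal differed by 3.95 (adjusted p = 0.000901), Cpt1b by 3.22 (0.00084), Ppargc1a by 2.47 (0.00522), Ppara by 2.35 (0.00888) and Pnpla2 by 0.95 (0.00943). In the other direction, Gpr50 fell by 5.28 in WAT and had a log2 change of −0.28 in BAT, a difference of −5.00 (adjusted p = 6.21e-06), followed by Atp6v0d2 (−4.83, adjusted p = 0.00125) and Cpa3 (−4.30, 0.0029). Ucp1 differed by 2.33, which did not pass (adjusted p = 0.122), but did without triple mutant WAT array 1 (3.05, adjusted p = 0.0391), while without triple mutant WAT array 3 it was 1.34 (adjusted p = 0.109). Elovl3 differed by 1.21 (adjusted p = 0.0546), and passed without ob/ob BAT array 3 (1.52, adjusted p = 0.0185) and with the filter on dim genes (0.0443). Lep did not pass (0.45, adjusted p = 0.211). Limma called the difference in 3002 genes (13.9%), 1183 positive and 1819 negative, and the WAT effect was the larger in 2457 of them (81.8%) and the BAT effect in 545. With each array centred on its median, which lowered every difference (by −0.11, median of all genes −0.05 in place of 0.07), 800 were positive and 2786 negative (22.3% positive in place of 39.4%). The count was 1779 without ob/ob WAT array 1, 1851 without ob/ob WAT array 2 and 1837 without ob/ob BAT array 3.

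By list, macrophage markers fell more in WAT than in BAT, with 17 of 25 genes lower (22 adjusted over the list alone). The median difference, WAT effect minus BAT effect, was −1.66 (camera adjusted p = 1.55e-13, adjusted p = 0.393 with an estimated correlation). Lysosome genes were lower in 21 of 32 and higher in 1 (22 and 1 adjusted over the list alone), and Lipa (−2.50), Hexa (−1.52) and Npc1 (−1.27), had no call in BAT. Their median difference was −0.75 (camera adjusted p = 1.41e-12, adjusted p = 0.393 with an estimated correlation). Complex I was positive in 25 of 38 genes (33 adjusted over the list alone), with a median of 0.77 (camera adjusted p = 1.77e-16, adjusted p = 0.393 with an estimated correlation). TCA cycle genes were positive in 17 of 22 (19 adjusted over the list alone), with a median of 1.0 (camera adjusted p = 1.48e-12, adjusted p = 0.393 with an estimated correlation). Complexes II and III were positive in 13 of 14 (14 adjusted over the list alone), with a median of 0.93 (camera adjusted p = 5.76e-11, adjusted p = 0.393 with an estimated correlation). ATP synthase was positive in 12 of 18 (17 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 1.53e-09, adjusted p = 0.393 with an estimated correlation). Mitochondrial fatty acid oxidation was positive in 15 of 22 (17 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 1.08e-08, adjusted p = 0.393 with an estimated correlation). Complex IV was positive in 12 of 21 (13 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 1.14e-07, adjusted p = 0.393 with an estimated correlation). Endothelial markers were positive in 12 of 17 (15 adjusted over the list alone), such as Tie1 at 0.77 in WAT and −0.41 in BAT. The endothelial median was 0.82 (camera adjusted p = 2.06e-08, adjusted p = 0.393 with an estimated correlation). Called members were 11 for macrophages without ob/ob WAT array 1, 9 (without ob/ob WAT array 2) or 8 (ob/ob BAT array 3 or triple mutant BAT array 1) for mitochondrial fatty acid oxidation, and 7 for endothelium (triple mutant WAT array 2 or triple mutant BAT array 2 or 3).

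Lipolysis genes were positive in 7 of 21 (12 adjusted over the list alone), with a median difference of 0.65 (camera adjusted p = 3.11e-05, adjusted p = 0.393 with an estimated correlation). Thermogenic genes were positive in 9 of 26 (10, with 1 negative, adjusted over the list alone), with a median of 0.52 (camera adjusted p = 7.95e-05, adjusted p = 0.393 with an estimated correlation). Glucose uptake and glycolysis had 5 positive and 1 negative of 23 (7 and 1 adjusted over the list alone). The median was 0.44 (camera adjusted p = 0.00189, adjusted p = 0.393 with an estimated correlation). Fatty acid and triglyceride synthesis had 9 positive and 1 negative of 28 (14 and 1 adjusted over the list alone). The median was 0.76 (camera adjusted p = 6.03e-05, adjusted p = 0.505 with an estimated correlation). Branched-chain amino acid catabolism was positive in 4 of 19 (11, with 1 negative, adjusted over the list alone), with a median of 0.58 (camera adjusted p = 8.44e-05, adjusted p = 0.515 with an estimated correlation). PPAR alpha targets were positive in 11 of 31 (12, with 1 negative, adjusted over the list alone), with a median of 0.38 (camera adjusted p = 0.00164, adjusted p = 0.515 with an estimated correlation). Adipocyte markers were positive in 6 of 18 (8, with 1 negative, adjusted over the list alone), with a median of 0.67 (camera adjusted p = 0.00189, adjusted p = 0.515 with an estimated correlation). Mesothelial markers were positive in 1 of 12 (1 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.0017, adjusted p = 0.486 with an estimated correlation). Without ob/ob WAT array 1 the median was 0.48 for fatty acid synthesis, 0.24 for PPAR alpha targets and 0.26 for adipocytes. Called members without ob/ob WAT array 3 were 13 in lipolysis, 9 in branched-chain amino acid catabolism and 8 in glycolysis (3 without ob/ob BAT array 3). PPAR alpha targets had 5 (without ob/ob WAT array 1), 6 (ob/ob BAT array 3) or 7 (ob/ob WAT array 2 or any triple mutant BAT array), and mesothelial markers 0 to 6 over the left-out arrays (6 without triple mutant WAT array 3).

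Cell cycle genes were negative in 2 of 33 (0 adjusted over the list alone), with a median difference of −0.77 (camera adjusted p = 4.00e-05, adjusted p = 0.563 with an estimated correlation). Cytokines were negative in 4 of 27 (4 adjusted over the list alone), with a median of −0.30 (camera adjusted p = 0.00887, adjusted p = 0.515 with an estimated correlation). Neutrophil and mast cell markers were negative in 4 of 15 (5 adjusted over the list alone), with a median of −0.11 (camera adjusted p = 0.0146, adjusted p = 0.393 with an estimated correlation). Both calls were lost with the filter on dim genes (adjusted p = 0.0786 for cytokines and 0.0946 for neutrophil and mast cell markers). Erythroid markers were positive in 4 of 10 (4 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.0132, adjusted p = 0.393 with an estimated correlation). With quantile normalization within each tissue the erythroid list did not pass (0.0536). The cell cycle median was −1.28 without ob/ob BAT array 1, with 26 genes called, and −0.50 without ob/ob BAT array 3, with 0, and 0 to 2 were called without each other array. The cytokine median was −0.47 without triple mutant WAT array 1, −0.48 without ob/ob BAT array 1 (9 called) and −0.56 without triple mutant BAT array 3. That of neutrophil and mast cell markers was −0.21 without ob/ob WAT array 2, −0.16 without triple mutant WAT array 3 or ob/ob BAT array 3, −0.24 without ob/ob BAT array 1 and 0.00 without ob/ob BAT array 2.

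For 5 further list differences the call was lost without single arrays. The mitochondrial ribosome had 6 of 73 genes positive (5 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.00309, adjusted p = 0.686 with an estimated correlation). It did not pass without triple mutant WAT array 3 (0.264, median 0.08), and 1 to 3 genes were called without ob/ob WAT array 1 or 2, ob/ob BAT array 3, or triple mutant BAT array 1 or 2. Peroxisomal fatty acid oxidation had 6 positive and 2 negative of 28 (11 and 3 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.019, adjusted p = 0.563 with an estimated correlation). It did not pass without triple mutant WAT array 3 (0.138, median 0.18) or triple mutant BAT array 1 (0.0576). Peroxins had 1 of 22 negative (1 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.0391, adjusted p = 0.563 with an estimated correlation). They did not pass without ob/ob WAT array 1 (0.14), triple mutant WAT array 3 (0.127), ob/ob BAT array 2 (0.0762) or triple mutant BAT array 1 (0.0714), and 4 were positive without ob/ob WAT array 3. The interferon response had 1 of 25 negative (0 adjusted over the list alone), with a median of −0.29 (camera adjusted p = 0.00404, adjusted p = 0.563 with an estimated correlation). It did not pass without triple mutant BAT array 1 (0.0915). Its median was −0.17 without that array or ob/ob WAT array 1, −0.49 without triple mutant WAT array 1 and −0.46 without ob/ob BAT array 1 or triple mutant BAT array 3, and 0 to 4 genes were called over the left-out arrays (4 without ob/ob BAT array 1). Immediate early genes had 3 of 20 negative (3 adjusted over the list alone), with a median of −0.19 (camera adjusted p = 0.0458, adjusted p = 0.515 with an estimated correlation). They did not pass without ob/ob WAT array 1 (0.115), triple mutant WAT array 1 (0.0834) or 3 (0.0985), ob/ob BAT array 1 (0.0565), or triple mutant BAT array 1 (0.115) or 2 (0.0561). Their call was also lost with the filter on dim genes (0.114) and with quantile normalization within each tissue (0.0777), and their median was −0.30 without triple mutant WAT array 2 and −0.31 without triple mutant BAT array 3.

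In all, 26 of 42 lists passed for the difference between tissues, 19 positive and 7 negative, 16 of them also with fry and none with an estimated correlation. With fry 10 calls were lost: adipocyte markers (0.0685), branched-chain amino acid catabolism (0.0662), PPAR alpha targets (0.0662), cell cycle (0.254), immediate early genes (0.129), cytokines (0.168), interferon response (0.272), mitochondrial ribosome (0.256), peroxins (0.118) and peroxisomal fatty acid oxidation (0.139). Skeletal muscle markers differed by 1.57 without passing (camera adjusted p = 0.0683), and passed without ob/ob BAT array 1 (3.25e-05), without triple mutant BAT array 1 (1.37e-05), with the filter on dim genes (0.0374) and with quantile normalization within each tissue (0.0272). White fat and visceral depot genes (0.0813) passed without ob/ob WAT array 2 (0.0360) or 3 (0.0277), without ob/ob BAT array 3 (0.0251) and with that normalization (0.0281), although Agt alone differed by 2.63 (limma adjusted p = 0.00199). T and NK cell markers (0.223) passed without ob/ob WAT array 3 (0.0329), and gonadal or testis markers (0.288) without triple mutant WAT array 1 (0.04997). Extracellular matrix genes did not pass (median difference −0.17, camera adjusted p = 0.21), nor did fibroblast markers (0.441), lipid droplet genes (0.483), cholesterol synthesis (0.664), hypoxia (0.445), stress response (0.199), developmental brown fat (0.199), mammary and skin (0.133), circadian clock (0.341), B cell (0.546), antioxidant (0.985) and Schwann cell lists (0.985).

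Genes that changed in both tissues mostly changed the same way. Eci3, Insig1, Mest and Nnat, for example, went the same way in both, with differences between the tissues that did not pass (limma adjusted p from 0.364 for Insig1 to 0.710 for Mest). In numbers, 1451 genes rose in both tissues, where independent lists of these sizes would share 396.6, and 908 fell in both against 251.9. Opposite directions were seen in 122 genes, 38 higher in WAT and lower in BAT and 84 the reverse. Of 2481 genes called in both tissues 2359 (95.1%) had the same direction. Across genes, the log2 changes of WAT and BAT correlated with Pearson's r = 0.61 and Spearman's rho = 0.44, where genes are not independent replicates.

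**Figure D3:**
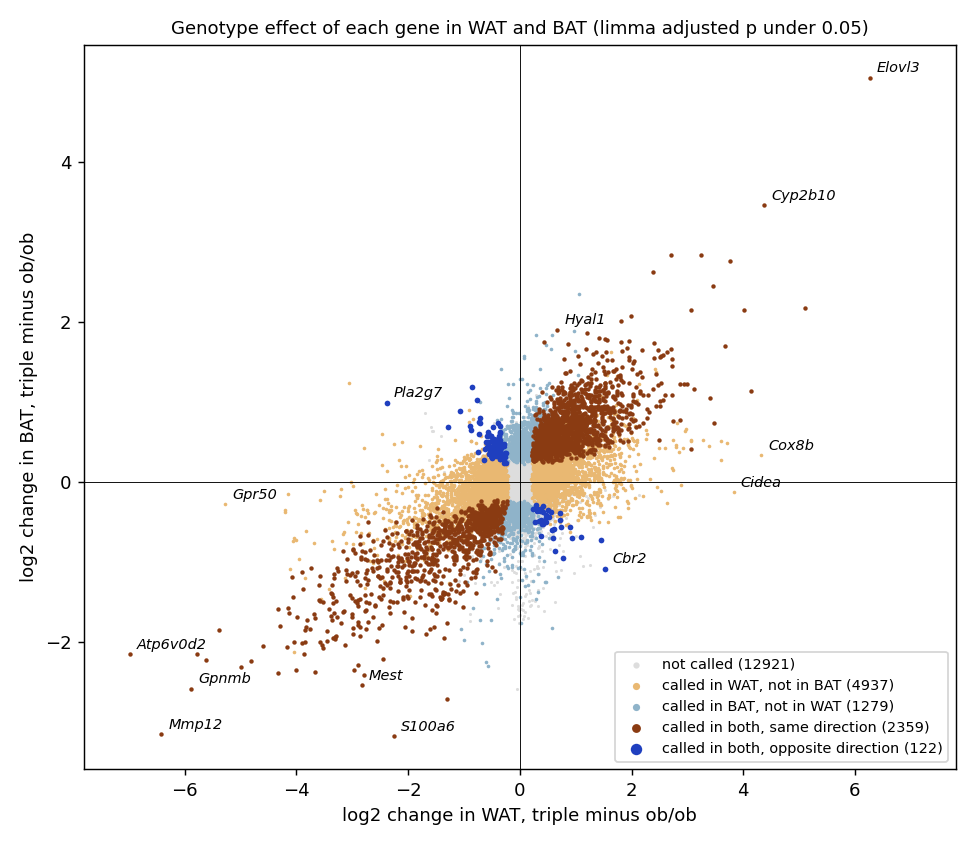
Log2 change, triple mutant minus ob/ob, of each gene in WAT (horizontal axis) against BAT (vertical axis), coloured by where limma called it. Most of the 2481 genes called in both tissues lie in the quadrants of equal sign (2359), and Elovl3 stands out at 6.26 and 5.05.

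Between tissues, the named genes higher in BAT of ob/ob mice were led by Ucp1 (log2 difference 6.26 from WAT, SE 0.67, limma adjusted p = 4.84e-05), Cidea (6.14, SE 0.32, 8.82e-07) and the muscle gene Atp2a1, a calcium pump (5.91, SE 0.94, 0.00057), and those higher in WAT by Gpr50 (−5.07, SE 0.18, 5.46e-08), Cpa3 (−3.97), Serpinb9b (−3.91) and Atp6v0d2 (−3.82). In triple mutants Ucp1 (3.94, SE 0.67, adjusted p = 0.00262) and Atp2a1 (4.35, adjusted p = 0.00974) were higher in BAT, and Slc5a7 (−4.28, adjusted p = 0.000431) and Agt (−4.01, SE 0.26, adjusted p = 8.21e-06) higher in WAT. Limma called 8053 genes (37.3%) between tissues in ob/ob mice, 3933 higher and 4120 lower in BAT, and 3107 (14.4%) in triple mutants, 1393 higher and 1714 lower. With each array centred on its median, the splits were 2836 higher and 4599 lower in ob/ob mice (38.1% in place of 48.8% higher) and 1851 and 1463 in triple mutants (55.9% in place of 44.8%). With the muscle marker mean as a covariate, added after the data were seen, the counts were 3088 and 1448. The count in triple mutants was 1835 without triple mutant WAT array 1 and 1840 without triple mutant WAT array 2.

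The authors' deposited table of changed genes listed 5945 probe sets in WAT (2783 up and 3162 down in triple mutants) and 1164 in BAT (837 up and 327 down). Of its 5038 genes tested here in WAT, limma called 4671 (92.7%) in the same direction, and 7 had the opposite sign. In BAT it was 929 of 1020 (91.1%), with 1 opposite. In the same direction, the authors listed 4671 of 7418 WAT calls and 929 of 3760 BAT calls.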

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

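The tests of macrophage share, array scale, muscle tissue, cross-hybridisation, exchanged labels and splits of paired arrays were chosen only after the results were seen. The genes given first were called by limma and the lists by camera at its preset correlation for a difference of the genotype effect between WAT and BAT. None of these 26 lists passed with an estimated correlation (adjusted p = 0.393 to 0.686), and 16 passed with fry. Values are WAT effect minus BAT effect on the log2 scale.

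Positive differences among genes of mitochondria and fat oxidation were those of Cox8b (3.99), Cpt1b (3.22), Cox7a1 (2.93), Acadvl (1.54), Atp5o (1.52), Idh3g (1.40), Ndufb8 (1.28), Bckdha (1.16), Cox5b (1.14), Cox6a1 (1.07), Uqcrfs1 (1.05), Ppargc1b (1.10), Esrrg (1.17), Ucp3 (1.04), Pecr (0.96) and Ndufa1 (0.88). Those of fat storage, release and their regulators were Cidea (3.95), Pck1 (2.74), Ppargc1a (2.47), Ces1d (2.36), Ppara (2.35), Acacb (2.09), Slc2a4 (1.66), Adig (1.62), G0s2 (1.34), Plin5 (1.08), Pnpla2 (0.95), Pde3b (0.95) and Dgat1 (0.90). Others were Tlcd4 (2.94), Agt (2.63), Cbr2 (2.62), Gsta4 (1.97), Asns (1.43), Tagln (1.47), Gys1 (1.34), Vegfa (1.25), Hbb-b1 (1.23), Tie1 (1.18), Dlk1 (1.0) and Robo4 (0.82). Negative differences in immune and lysosomal genes were those of Atp6v0d2 (−4.83), Cpa3 (−4.30), Serpinb9b (−3.86), Il7r (−3.55), Pla2g7 (−3.38), Il1rn (−3.34), Gpnmb (−3.31), Mmp12 (−3.27), Mcpt4 (−3.08), Stap1 (−2.69), Ctsk (−2.63), Itgax (−2.56), Lipa (−2.50), Dcstamp (−2.14), Jchain (−2.08), Galc (−1.97), Hexa (−1.52) and Npc1 (−1.27). Others were Gpr50 (−5.00), Atf3 (−3.03), Sfrp5 (−2.94), Gatm (−2.20), Egr2 (−2.04), Acsl5 (−1.97), Postn (−1.96), Hyal1 (−1.23), Myc (−0.85) and Nfe2l2 (−0.85).

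Among lists the median difference was 1.0 for the TCA cycle, 0.93 for complexes II and III, 0.91 for mitochondrial fatty acid oxidation, 0.82 for endothelium, 0.77 for complex I, 0.76 for fatty acid synthesis, 0.73 for ATP synthase, 0.70 for complex IV, 0.67 for adipocytes, 0.65 for lipolysis, 0.58 for branched-chain amino acids, 0.55 for mesothelium, 0.52 for thermogenic genes, 0.44 for glycolysis, 0.40 for peroxisomal oxidation, 0.38 for PPAR alpha targets, 0.27 for peroxins, 0.24 for erythroid cells and 0.23 for the mitochondrial ribosome. It was −1.66 for macrophages, −0.77 for the cell cycle, −0.75 for lysosomes, −0.30 for cytokines, −0.29 for interferon, −0.19 for immediate early genes and −0.11 for neutrophils and mast cells. Of 100 splits within both tissues 6 gave as many genes as the real 3002 (highest other 4465), but the 5 others all kept the real WAT labels and with them the WAT effect, and the highest without those labels was 133, so this decides nothing on chance. For lists, 37 splits gave as many as the real 26 (highest other 33), and chance was not excluded. With each pair of a WAT and a BAT array of one number moved together, 1 of 10 splits, the real one, gave as many genes (highest other 119) or lists (20), and 10 are too few for a share under 0.05. Of 100 splits 1, the real one, gave as many genes called the same way in both tissues (2359, highest other 37), but only 2 of the 99 others called any gene in both tissues, so this decides nothing either.

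The 10 splits of 6 arrays are too few for a share under 0.05. The real split called 7418 genes in WAT (highest other 0), 3760 in BAT (253), 8053 between tissues in ob/ob mice (0) and 3107 in triple mutants (0), with 31 lists in WAT (29) and 28 in BAT (27), and no other split gave as many. Camera at its preset correlation thus also called many lists under other groupings, while fry called 37 in WAT (highest other 0) and 22 in BAT (1).

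Probe sets that name no gene took part in no comparison, and limma called 459 of 3344 (13.7%) in WAT and 210 (6.28%) in BAT. Of 5222 intron control probe sets it called 409 (7.83%) and 0.

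Mitochondrial and adipocyte genes rose in WAT while macrophage genes fell. A lower macrophage share alone would raise other cell markers alike. But fibroblast and preadipocyte markers fell (array means 8.74 to 8.76 in ob/ob, 8.14 to 8.52 in triple mutants), which argues against it. The adipocyte median lay 1.5 higher (log2, bootstrap SE 0.29 over genes alone). The exon control median change of 0.0727 (intron −0.13) against 1.24 for complex I argues against a shift of scale. A macrophage loss beside changes within adipocytes or a higher adipocyte share, and an effect of the labelled genotype, stay open, untested.

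Skeletal muscle transcripts differed between BAT arrays of both genotypes. All 21 muscle markers had the same 3 highest BAT arrays (ob/ob arrays 2 and 3 and triple mutant array 1), where a given trio has a chance share of 0.05, and their median range over the BAT arrays was 4.89. This is consistent with muscle tissue in some samples, from dissection or otherwise. Muscle content as the source of the BAT genotype effect is argued against, since 3086 of 3760 calls (82.1%) stayed in the same direction with the marker mean as a covariate. No biological explanation was tested.

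The Cidea signal rose in WAT of mice labelled as lacking Cidea. Cross-hybridisation of Cidec transcripts would raise both signals, but Cidec changed by −0.44 (log2, SE 0.16) against 3.83 for Cidea. An exchange of genotype labels in WAT alone is argued against by the numbers shared across tissues, since no pairing across genotypes had a mean correlation of deviations above 0.0544 (highest single r 0.0992), against 0.19 as labelled (lowest single r 0.15). An exchange in both tissues cannot be told from transcription of a mutated Cidea locus, since the deletion's position relative to the probes is unknown here. Cidea in BAT did not pass (log2 −0.13, SE 0.32 pooled with WAT, limma adjusted p = 0.365 in BAT alone). A remaining transcript in mutant tissue may account for the signal, untested.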

How the results depend on the processing

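The muscle covariate and the block in the list tests of the difference were chosen after the data were seen. With at least 1.5-fold required, which cannot raise a count, called genes were 4450 in WAT, 1809 in BAT, 4063 and 1766 between tissues in ob/ob and triple mutants, and 1266 shared by WAT and BAT. Array weights gave 5471 genes for the difference between tissues and 5521 between tissues in triple mutants. With the muscle covariate 3088 and 1448 genes were called between tissues in ob/ob and triple mutants, and the muscle list in BAT, lower before, did not pass (camera adjusted p = 0.871), since the covariate is the mean of that list. The causes of the other shifts were not tested. With an estimated correlation 0 lists passed in WAT, BAT or the difference (lowest adjusted p 0.15, 0.216 and 0.393), and fry called 37, 22 and 17 in place of 31, 28 and 26. Cidec in WAT passed with quantile normalization (−0.51). Leaving out each array gave 5977 to 7064 genes in WAT, 2466 (without triple mutant BAT array 3) to 3784 in BAT, 1779 to 3398 for the difference, 5921 to 7703 between tissues in ob/ob mice and 1835 to 3585 in triple mutants. Cidea in WAT ranged from 3.38 to 4.18, and Cidec from −0.60 (without ob/ob WAT array 1, where it passed) to −0.29.

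Within a tissue the replicate numbers pair nothing in the data (correlations of deviations −0.05, 0.07 and 0.11 in WAT, −0.43, −0.24 and −0.23 in BAT), and the replicate block gave 6811 genes in WAT and 2967 in BAT, the interferon list passed in WAT (0.0123) and Pparg did not (0.0797). Across tissues, with a block of genotype and number, 3641 genes were called for the difference, 8599 in ob/ob and 3486 in triple mutants, and the same number of lists (26). That block changed no list call, and for named genes it only added calls of the difference (Ckb, Col3a1, Fos, Lgals3, Pcolce, Ppp1r3c, Rrm2, S100a6, Scd1 and Slc6a8). Under every setting that gives a p, 122 of the 123 called genes named for WAT kept their call, 76 of 85 for BAT and 69 of 69 for the difference, and apart from the estimated correlation 29 of 31 lists in WAT, 19 of 28 in BAT and 14 of 26 for the difference. The alternative of the deposited matrix in place of the authors' expression table was not run, because the matrix was the source of all values. Signal over background limits dim genes: 19.5% to 32.3% of genes per array lay above the highest antigenomic control, and limma recovered 46% of simulated 1.5-fold changes in WAT and 62% in BAT.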

Other observations

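The gene groups and genes of these first 2 paragraphs, and the tests of shared numbers and of neighbouring genes, were chosen only after the values were seen, so the 8 groups are not independent evidence, and each adjusted p is over these 8. In WAT glycogen genes rose (8 of 9, median log2 change 1.40, camera adjusted p = 0.000296), such as Gys1, glycogen synthase (1.75), and Ppp1r3c (2.07), as did regulators of mitochondrial biogenesis (7 of 9 with 1 lower, 0.67, 0.000781), among them Ppargc1b (1.61) and Esrrg (1.5). Lower were cytosolic ribosomal proteins (58 of 82 with 2 higher, −0.38, 1.92e-12), genes typical of osteoclasts and giant cells (6 of 10 with 1 higher, −1.86, 5.25e-05), chaperones of the endoplasmic reticulum (10 of 13 with 1 higher, −0.65, 0.000264), including Sdf2l1 (−2.12), creatine genes (4 of 7, −0.84, 0.0415), with Gatm (−2.42), Slc6a8 (−1.90) and Ckb (−1.55), and genes of antigen presentation by MHC class II (4 of 6, −0.76, 0.0017). With an estimated correlation each had adjusted p = 0.109, or 0.189 for MHC class II. Beta tubulins did not pass in WAT (4 lower and 2 higher of 8, camera adjusted p = 0.0705).

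In BAT glycogen genes (3 of 9 higher, median 0.46, camera adjusted p = 0.00473) and regulators of mitochondrial biogenesis (5 of 9, 0.39, 0.000362) rose. Lower were ribosomal proteins (32 of 82 with 1 higher, −0.26, 2.46e-11), giant cell genes (5 of 10, −0.64, 0.000652), chaperones (4 of 13 with 1 higher, −0.31, 0.0169), beta tubulins (5 of 8, −0.59, 0.000652) and MHC class II (4 of 6, −1.03, 9.12e-05), with H2-Eb1 at −1.36 and Cd74 at −1.37. With an estimated correlation the adjusted p was 0.127 to 0.231. Creatine genes did not pass in BAT (median −0.31, camera adjusted p = 0.11). With arrays centred 16 ribosomal proteins and 2 chaperones were lower, and with quantile normalization within the tissue 53 ribosomal proteins were lower and 2 biogenesis and 1 glycogen genes higher. The difference between tissues passed for giant cell genes (median −1.40, camera adjusted p = 0.00147), chaperones (−0.34, 0.0203), glycogen (0.66, 0.0238) and ribosomal proteins (−0.10, 0.0238, but −0.21 centred and −0.01 with quantile normalization), with adjusted p from 0.378 to 0.627 with an estimated correlation. It did not pass for creatine (0.226), biogenesis (0.29), MHC class II (0.666) and tubulins (0.964). A few genes went opposite ways: Pla2g7 fell in WAT (−2.39) and rose in BAT (0.99), as did Acsl5 (−1.29 and 0.68) and Galc (−1.07 and 0.89), and Cbr2 (1.53 and −1.08) and Tagln (0.91 and −0.56) did the reverse.

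The numbers in the titles may mark animals sampled in both tissues: of 36 pairings within genotype 1, the labelled one, had the highest mean correlation of deviations (0.19, highest other 0.12, exact permutation p = 0.0278). Genes within 5 Mb of Cidea and Cidec were called in 55 of 150 (36.7%, against 34.3% elsewhere) in WAT and 31 (20.7% against 17.4%) in BAT, which does not tell whether variants carried with the mutated loci change nearby genes (Fisher's exact two-sided p = 0.547 and 0.281).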
